A study of Mus musculus with 8 samples.

How the data were processed

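Polyadenylated RNA of A223 cells was profiled by RNA sequencing in 8 libraries, 2 replicates of each of 4 groups: parental or PRDX6 knockdown cells, with DMSO at 0 h or 100 nM largazole at 18 h. Per the labels' protocols, RNA was isolated with a column kit and stranded libraries were made after polyA selection. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, its strand setting and the gene annotation are not given in the sources used here. The deposited values are estimated counts per gene symbol, as shown by values that are never negative, mostly whole with a minority of fractions, and that sum to different totals per library. These deposited expected counts were not normalized. They were rounded to whole numbers before testing.

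Of 24411 genes, 27 had symbols turned into dates by spreadsheet software and could not be named. Of these 21 were tested, and they held at most 0.312% of the counts of a library. The mitochondrially encoded genes were not analysed here. Coordinates and transcript sequences came from GENCODE M21 on GRCm38, the same assembly as mm10, and exon overlaps between genes were taken from it. Reads of overlapping genes cannot be told apart where the counting did not use strand.

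The main test was edgeR 4.0.16's quasi-likelihood F test, two-sided, with TMM scaling and filterByExpr (minimum count 10, minimum total 15), fitted to all 8 libraries with 1 mean per group so that the groups share 1 estimate of the spread. Adjusted p is by the Benjamini-Hochberg method over the 12517 genes tested, with a threshold of 0.05, and the common biological coefficient of variation was 0.0946. SE is the size of the log2 fold change divided by the square root of F. The 6 contrasts fitted were largazole in each genotype, the knockdown in each condition, the difference between the largazole responses and the mean largazole response, which was used to choose responding genes. CPM values are scaled by TMM, and principal components used log2 CPM with a prior count of 2. Where a group held 0 counts, folds are lower bounds against a floor of 3 counts per library. With 1 to 3 counts a ratio is given with its exact 95% binomial interval.

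Gene lists, 46 in all, were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and beside it with an estimated correlation, where at least 5 members were tested. Fry was run as an alternative. Camera's p was adjusted over all lists within a contrast. Of 1017 list members 992 matched a gene by symbol, 10 by an older symbol and 15 had no match. The design, the tests, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The rule named Prdx6, the 10 most raised and 10 most lowered passing genes per contrast with at least 5 CPM and separated replicates, up to 4 passing members of each described list, Hdac1, Hdac2, Hdac3, Cdkn1a, Gpx4 and Slc7a11. For reasons of length not all genes that the rule names are described. In the difference between responses, Gm5424 was named after its values were seen.

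The analysis was tested on simulated data with known changes. The main test recovered 74.6% of 1.5-fold and 95.5% of 2-fold changes for largazole in parental cells (12275 genes), 55.2% and 97.0% for largazole in KD cells (12268 genes), 52.2% and 92.5% for the knockdown in DMSO (12268 genes), 55.2% and 92.5% for the knockdown under largazole (12269 genes), and 16.4% and 71.6% for the difference between responses (12262 genes). All simulated 4-fold changes were recovered in each of these 5. The share of calls that were false lay between 4.12% and 8.63%. Only 200 genes, all of at least 5 CPM, were changed, genes were drawn independently, and all groups had the same spread. In the data far more genes changed, and the spread between replicates differed between groups. The SD of the log2 difference between replicates, over genes with a mean of at least 5 CPM, was 0.194 to 0.359. These rates may therefore not hold for the data.

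The alternatives fixed in advance were RLE and upper-quartile scaling, library totals only, no filter and a stricter filter on low counts. The stricter filter required both a minimum count of 30 and at least 1 CPM in every library of at least 1 group. Also fixed in advance were DESeq2 1.42.0, limma-voom, the older quasi-likelihood method and a fit of only the libraries compared. So were the replicate number as a block and leaving out each library in turn. Leaving out a library leaves 1 library in its group, which is then assumed to vary like the other groups. Removal of Rn45s, and removal of trends with transcript length alone or with GC content as well (lowess, span 0.3), were added after seeing the data. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. Each library held at least 13020492 counts. Counting error fell as counts rose, still mattered near 5 CPM and was largest for genes with counts near 0 in a group.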

Results

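Polyadenylated RNA was sequenced from A223 cells, a mouse squamous cell carcinoma line, either parental or with a knockdown of PRDX6 (KD). PRDX6 is a peroxiredoxin that reduces hydrogen peroxide and phospholipid hydroperoxides. Each genotype was sampled with DMSO at 0 h and after 18 h of 100 nM largazole, an inhibitor of class I histone deacetylases (HDACs), which gave 4 groups of 2 replicate libraries. Total estimated counts per library ranged from 13020492 to 15613216 over 24411 genes, of which 12517 had enough counts to be tested. The first principal component held 70.4% of the variance in log2 counts scaled to library size (CPM) and separated largazole from DMSO libraries, and the second, with 18.3%, separated the genotypes. Replicates differed by more than sampling noise in every group. Chi-square per degree of freedom was 2.02 in parental DMSO, 10.9 in parental largazole, 10.1 in KD DMSO and 46.2 in KD largazole. This measure includes Rn45s, the abundant gene described next, whose difference between replicates raises it. Over genes with a mean of at least 5 CPM, the SD of the log2 difference between replicates was 0.194, 0.218, 0.207 and 0.359, in that order. Rn45s, the ribosomal RNA precursor, differed between the replicates of 3 groups: 7739 and 950 CPM in parental largazole, 9963 and 2549 CPM in KD DMSO and 23915 and 742 CPM in KD largazole, against 1353 and 1212 CPM in parental DMSO. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Drug and time changed together in the largazole comparisons, and KD cells were compared with parental cells, with no non-targeting construct analysed here.

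The targeted gene was measured first, to check the knockdown labels. Prdx6 (chromosome 1, 161240112 to 161251219, minus strand, GRCm38, protein-coding) was lower in all 4 KD libraries than in all 4 parental ones. Its counts were 4016 and 4189 in parental DMSO, 3774 and 3533 in parental largazole, 1315 and 1075 in KD DMSO and 1040 and 962 in KD largazole. These correspond to 290 ± 10.1, 245 ± 17.1, 82.9 ± 5.23 and 73.0 ± 11.4 CPM (SD, n = 2 libraries), so that KD cells held 28.6% of the parental level in DMSO and 29.8% under largazole. Prdx6 fell with the knockdown by log2 fold changes of -1.81 ± 0.11 in DMSO (SE, adjusted p = 1.41e-05) and -1.75 ± 0.11 under largazole (adjusted p = 1.76e-05, edgeR's quasi-likelihood test). The difference between genotypes in the response of Prdx6 to largazole was 0.06 on the log2 scale (adjusted p = 0.976). The response itself was -0.24 in parental (adjusted p = 0.083) and -0.19 in KD cells (adjusted p = 0.194). It passed in parental cells without KD largazole replicate 1 (adjusted p = 0.00442) or replicate 2 (adjusted p = 0.00318), and in KD cells without KD largazole replicate 1 (adjusted p = 0.00375).

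**Figure D1:**
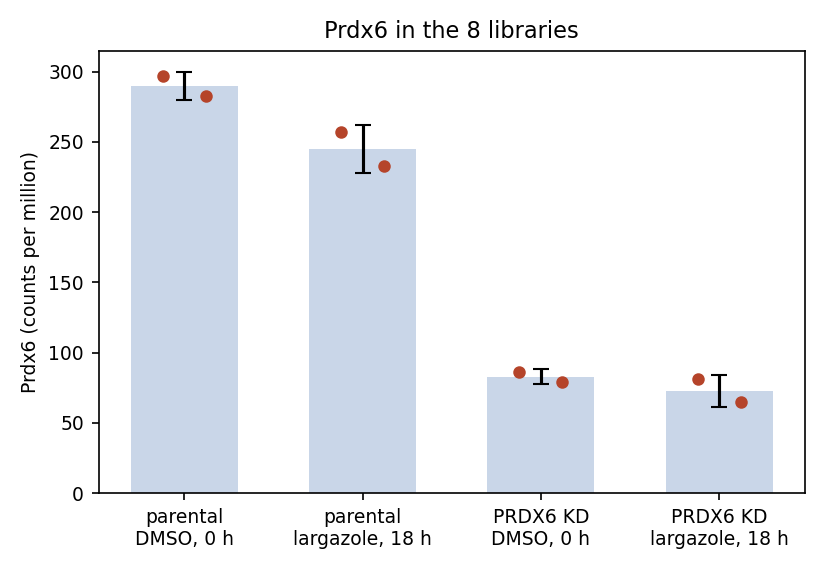
Prdx6 level in CPM (vertical axis) in the 4 groups (horizontal axis), with bars at the mean of 2 libraries, error bars of 1 SD and points for single libraries. The KD libraries lay at 28.6% of the parental mean in DMSO and 29.8% under largazole.

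The knockdown was first compared with parental cells in DMSO, the comparison that asks what lowering PRDX6 does without the drug. All 32 tested interferon-stimulated genes, the antiviral genes induced by interferon signalling, were higher in KD than in parental cells, a list whose call was lost with an estimated correlation (camera, adjusted p = 0.208). Ifi44 rose from 0.603 ± 0.0889 to 36.5 ± 23.96 CPM, Irf7, a transcription factor that drives type I interferon genes, from 1.51 ± 0.152 to 48.6 ± 28.6 CPM, and Ifit1, which binds viral RNA, from 2.58 ± 0.117 to 36.2 ± 11.1 CPM (SD, n = 2). Genes of endoplasmic reticulum (ER) chaperones and the unfolded protein response were lower, with 15 of 20 falling, among them Hspa5, the main ER chaperone, from 2334 ± 24.4 to 1260 ± 52.1 CPM. Of mesenchymal and extracellular matrix genes 15 of 25 and of NF-kB and cytokine genes 9 of 22 were higher, and 16 of 27 genes of ribosome biogenesis were lower.

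In all, 1380 genes differed in DMSO (877 higher and 503 lower in KD, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 365 of them higher and 42 lower by at least 2-fold, and 3104 had an unadjusted p under 0.05. With only the libraries compared, 1745 were higher and 1521 lower, so the size of the excess of higher genes depended on the fit. For the interferon-stimulated genes the count adjusted over the list alone was also 32 (camera, adjusted p = 5.87e-27, and adjusted p = 0.208 with an estimated correlation). The KD DMSO libraries differed in these genes, with Ifi44 at 53.5 CPM in replicate 1 and 19.6 CPM in replicate 2, the same libraries in which Rn45s stood at 9963 and 2549 CPM. Exons of Irf7 overlap those of Phrf1, and the strand setting of the counting was not given in the sources used here. Iigp1, an interferon-induced GTPase, had 159 counts in KD and 2 in parental DMSO, a ratio of 78.4 (95% interval 21.3 to 653), and Oas2, which activates RNA decay, 160 and 3, a ratio of 52.6 (17.7 to 258). Intervals and floors cover counting error only. Steap4, a metalloreductase, rose from 0.643 ± 0.241 to 16.4 ± 0.312 CPM. In MHC class I antigen presentation, 6 of 16 genes rose, 7 when adjusted over the list alone (camera, adjusted p = 7.17e-05, and adjusted p = 0.502 with an estimated correlation). Among them were H2-T23 (log2 fold change 1.79 ± 0.21) and the peptide-loading factor Tapbp (0.89 ± 0.12).

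Among the ER chaperone and unfolded protein response genes, Sdf2l1 (-1.15 ± 0.10), Creld2 (-1.11 ± 0.10), the disulfide isomerase Pdia4 (-0.995 ± 0.074) and Hspa5 (-0.89 ± 0.07) fell, while Dnajb9, Edem1, Hspa13, Syvn1 and Xbp1 did not pass. The count adjusted over the list alone was 15, and the list's call held with an estimated correlation (adjusted p = 0.0456, against 1.62e-10 with the preset one). Ribosome biogenesis had 16 of 27 genes lower, 19 adjusted over the list alone (adjusted p = 0.0456 with an estimated correlation), including the nucleolar protein gene Nolc1 (-0.53 ± 0.07). Of 25 mesenchymal genes 15 rose, 17 adjusted over the list alone (adjusted p = 0.0456 with an estimated correlation). The matrix protease Mmp3 rose by 2.44 ± 0.12, the surface marker Thy1 by 1.97 ± 0.11, the proteoglycan Dcn by 1.26 ± 0.08 and Col6a1 by 1.02 ± 0.09. Of 22 NF-kB and cytokine genes 9 rose, 11 adjusted over the list alone (adjusted p = 0.0456 with an estimated correlation). Cxcl5 rose by 3.44 ± 0.35, and the monocyte chemoattractants Ccl2 and Ccl7 by 1.87 ± 0.13 and 1.68 ± 0.14. Of 17 targets of YAP and TEAD 5 fell and 1 rose, 8 lower when adjusted over the list alone (camera, adjusted p = 0.0011, and adjusted p = 0.375 with an estimated correlation). Ctgf (-1.35 ± 0.17) and Igfbp3 (-1.11 ± 0.12) were among those that fell. Single genes that fell also included Sema6a (-1.86 ± 0.23), Lama5, a laminin chain (-1.62 ± 0.24), and Ptchd1 (-1.51 ± 0.16).

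The number of changed genes in DMSO depended on single libraries. It was 411 and 398 without parental DMSO replicate 1 and replicate 2, 456 and 601 without KD DMSO replicate 1 and replicate 2, and 2959 and 2969 without KD largazole replicate 1 and replicate 2. Without these libraries in that order, the ribosome biogenesis count was 1, 1, 1, 3, 21 and 21, and it was 9 and 10 without parental largazole replicate 1 and replicate 2. The mesenchymal count was 9 without either parental DMSO library. The NF-kB count was 15 and 14, and the YAP count 8, without KD largazole replicate 1 and replicate 2. The MHC class I count was 2 without parental DMSO replicate 1, 3 without KD DMSO replicate 1 and 10 without KD largazole replicate 1. The cell cycle inhibitor gene Cdkn1a was higher by 0.51 ± 0.09 (adjusted p = 0.00556) and missed the threshold without parental DMSO replicate 1 or 2 or KD DMSO replicate 1 (adjusted p = 0.0768, 0.0809 and 0.075). Gpx4, the lipid hydroperoxide reductase, had a log2 fold change of 0.00 (adjusted p = 1), Slc7a11, the cystine transporter, 0.30 (adjusted p = 0.171), Hdac1 0.16 (adjusted p = 0.223), Hdac2 -0.18 (adjusted p = 0.212) and Hdac3 0.08 (adjusted p = 0.618). Hdac2 passed without KD largazole replicate 1 (adjusted p = 0.0491) or replicate 2 (adjusted p = 0.0379).

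**Figure D2:**
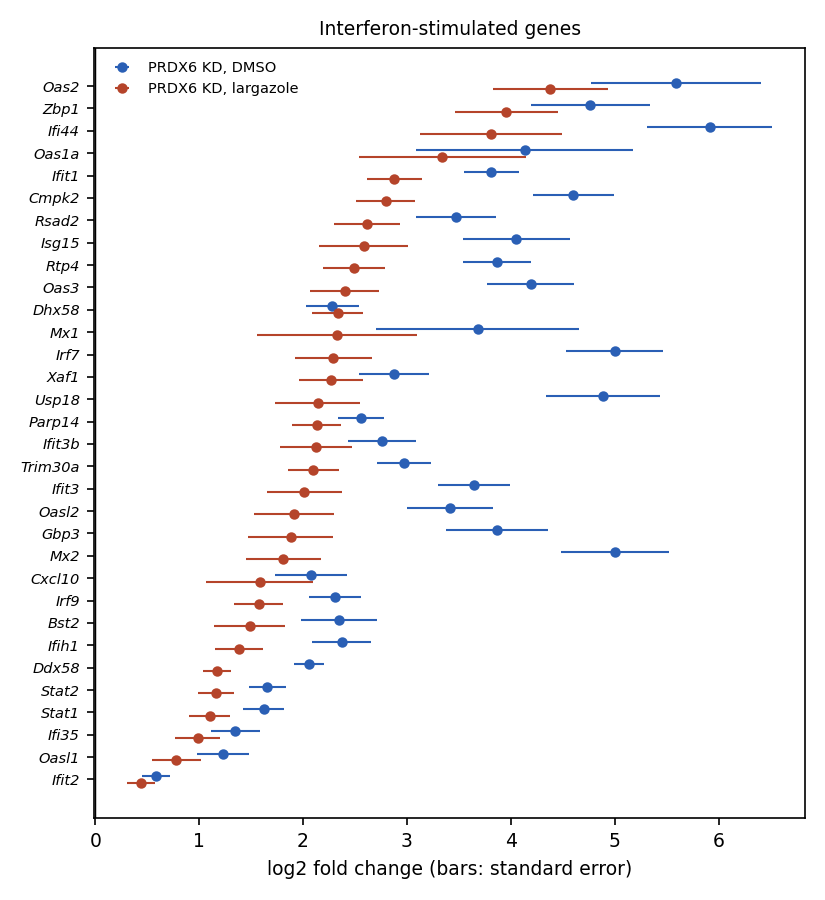
Log2 fold changes of KD against parental cells (horizontal axis) for the 32 tested interferon-stimulated genes (vertical axis), in DMSO (blue) and under largazole (red), with bars of 1 SE. In DMSO 32 genes passed, and under largazole 30.

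The same comparison after 18 h of largazole asks how the genotypes differ under the drug. The ER chaperone genes were again lower in KD cells, with Hspa5 at 451 ± 0.453 CPM against 2637 ± 27.9 in parental cells (SD, n = 2). Interferon-stimulated genes were again higher, 30 of 32, with Ifit1 at 22.7 ± 1.62 against 3.07 ± 0.876 CPM and Zbp1, a sensor of Z-form nucleic acids, at 22.5 ± 3.07 against 1.45 ± 0.460 CPM. Genes of DNA replication and S phase were lower in KD cells, 26 of 33, where 11 were already lower in DMSO. The count in DMSO was lower without any 1 DMSO or parental largazole library. The list's median log2 fold change in DMSO was -0.244, and between -0.271 and -0.243 without any 1 library. Its call in DMSO was lost with an estimated correlation (camera, adjusted p = 0.139). Of 24 genes of the integrated stress response 17 were lower. Genes of glycolysis and the hypoxia response were higher, 14 of 27, where 5 were already higher in DMSO. Among them Bnip3, a mitophagy receptor, stood at 231 ± 23.7 against 70.3 ± 5.42 CPM. With an estimated correlation the calls of the interferon, integrated stress response and glycolysis lists were lost (camera, adjusted p = 0.225, 0.166 and 0.225).

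Under largazole 2293 genes differed between genotypes (1065 higher and 1228 lower in KD, 327 and 141 by at least 2-fold, edgeR's quasi-likelihood test), and 3988 had an unadjusted p under 0.05. The numbers higher and lower were 1144 and 1139 with upper-quartile scaling and 535 and 430 with only the libraries compared. Which direction held more genes thus depended on the setting. Of the interferon-stimulated genes 30 of 32 rose, 32 adjusted over the list alone (camera, adjusted p = 1.81e-18, and adjusted p = 0.225 with an estimated correlation). The 2 that missed were Cxcl10 (1.58, adjusted p = 0.0577) and Mx1 (2.33, adjusted p = 0.0559). The KD largazole libraries, in which these lists were measured, held Rn45s at 23915 and 742 CPM. Of the ER chaperone genes 18 of 20 fell, 19 adjusted over the list alone (adjusted p = 0.0312 with an estimated correlation). They included Hspa5 with -2.55 ± 0.07, Creld2 with -2.24 ± 0.11, Pdia4 with -1.98 ± 0.08 and Herpud1, a factor of ER-associated degradation, with -1.75 ± 0.09. Hspa13 (-0.06) and Xbp1 (-0.21) did not pass. S phase genes fell with a median of -0.73, 27 adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation). Among them were the replication licensing genes Cdc6 (-1.49 ± 0.16) and Orc1 (-1.27 ± 0.16) and the cyclins Ccne1 (-1.26 ± 0.16) and Ccne2 (-1.21 ± 0.14). Ribosome biogenesis had 22 of 27 genes lower, 25 adjusted over the list alone (adjusted p = 0.0312 with an estimated correlation), with Rrp12 and Rrs1 at -0.88 ± 0.14 and -0.88 ± 0.09. Homologous recombination and Fanconi genes fell in 16 of 18 cases, 18 adjusted over the list alone (camera, adjusted p = 2.53e-11, and adjusted p = 0.0714 with an estimated correlation), with the checkpoint kinase Chek1 at -1.04 ± 0.13.

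Mesenchymal genes rose in 13 of 25 cases, 15 adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation), with Mmp3 at 1.42 ± 0.14, Col3a1 at 1.38 ± 0.09 and Dcn at 1.24 ± 0.08. Of the NF-kB and cytokine genes 11 of 22 rose and 1 fell, 13 risen when adjusted over the list alone (adjusted p = 0.04996 with an estimated correlation). The alarmin Il33 stood at 2.52 ± 0.08 and Cxcl5 at 2.44 ± 0.22. In glycolysis and hypoxia 17 genes rose when adjusted over the list alone (camera, adjusted p = 1.71e-08, and adjusted p = 0.225 with an estimated correlation). Bnip3 stood at 1.72 ± 0.10, Vegfa at 1.13 ± 0.08 and the carbonic anhydrase Car9 at 1.04 ± 0.16. In the integrated stress response 17 genes fell and 3 rose, 18 fallen when adjusted over the list alone (camera, adjusted p = 2.65e-06, and adjusted p = 0.166 with an estimated correlation). Ddit3 at -1.67 ± 0.17, the pseudokinase Trib3 at -1.48 ± 0.12 and Slc7a11 at -0.96 ± 0.15 fell, and Ddit4, an inhibitor of mTORC1 signalling, rose by 1.08 ± 0.12. Of the YAP and TEAD targets 6 of 17 fell and 1 rose, 10 lower when adjusted over the list alone (camera, adjusted p = 0.000247, and adjusted p = 0.225 with an estimated correlation). Ctgf stood at -2.05 ± 0.16 and Cyr61 at -1.35 ± 0.09. Single genes with large changes were Dpt, a matrix protein (4.15 ± 0.34), Steap4 (3.40 ± 0.22), Spns2, a sphingosine-1-phosphate transporter whose exons overlap those of Mybbp1a (-2.83 ± 0.28), and Arhgef10 (-1.98 ± 0.19). Cdkn1a had a change of 0.28 (adjusted p = 0.0568) and Gpx4 of 0.14 (adjusted p = 0.529), and both passed without KD largazole replicate 2 (adjusted p = 0.000782 and 0.000947). Hdac1, Hdac2 and Hdac3 had changes of -0.08, 0.03 and -0.15 (adjusted p = 0.498, 0.837 and 0.283).

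Without parental largazole replicate 1 and replicate 2 the number of genes differing under largazole was 847 and 837, the integrated stress response count 9 and 9 and the homologous recombination count 9 and 8. The number of genes was 4175 without KD largazole replicate 2. The NF-kB count was 7 without parental largazole replicate 1, and the call of the 1 NF-kB gene that fell was lost without parental largazole replicate 2. The glycolysis and hypoxia count was 8 without parental largazole replicate 2 and 23 without KD largazole replicate 2, and the YAP count 11 without KD largazole replicate 2. Of the genes higher in KD cells 593 were shared between DMSO and largazole, where independent lists would share 74.6, and of the lower genes 374, where independent lists would share 49.3. The 2 knockdown comparisons have no library in common, and across the tested genes, which are not independent replicates, their log2 fold changes had Pearson's r = 0.557 and Spearman's rho = 0.629.

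**Figure D3:**
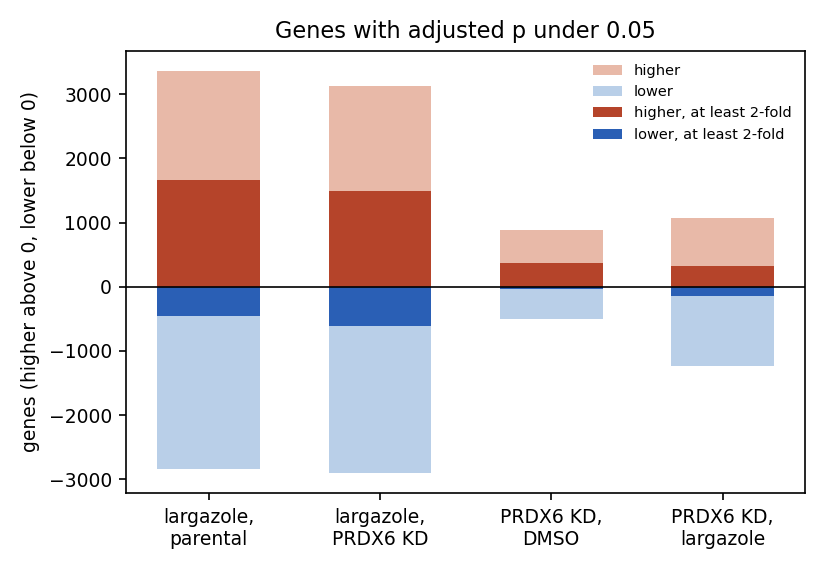
Number of genes with an adjusted p under 0.05 (vertical axis, higher above 0 and lower below 0) in 4 comparisons (horizontal axis), with dark parts for changes of at least 2-fold. Largazole changed 6205 genes in parental and 6029 in KD cells, and the knockdown 1380 in DMSO and 2293 under largazole.

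Largazole for 18 h was compared with DMSO at 0 h in parental cells and, separately, in KD cells, which asks what the drug does in each genotype. In both genotypes all 32 tested genes of mitosis and the G2/M phase and all 18 of homologous recombination and the Fanconi pathway fell, together with most genes of S phase and cholesterol synthesis. Genes of neuronal character rose in 13 of 19 cases in each genotype, genes of epithelial junctions in 10 of 12 and genes of keratinocyte differentiation in 7 of 10 in parental and 6 of 10 in KD cells. The calls of all 7 of these lists were lost in both genotypes with an estimated correlation (camera, adjusted p = 0.0515 to 0.171). Here and below the counts are of tested members, and other members of the neuronal, junction and keratinocyte lists were not tested. Some tested members entered only through the largazole libraries, such as Vgf with 3 counts in parental and 2 in KD DMSO. The filter thus favoured a rise in these shares. Cadm4, an adhesion molecule, went from 0.559 ± 0.163 to 98.6 ± 0.130 CPM in parental cells and from 0.393 ± 0.277 to 95.4 ± 3.83 in KD cells, and Stmn2, a neuronal microtubule regulator, from 0.138 ± 0.0908 to 35.8 ± 0.876 CPM in parental cells (SD, n = 2). Esm1, a proteoglycan of endothelium, fell from 144 ± 4.19 to 15.9 ± 1.24 CPM in parental cells.

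Largazole changed 6205 genes in parental cells (3366 higher and 2839 lower, 1668 and 462 by at least 2-fold) and 6029 in KD cells (3124 and 2905, 1493 and 605 by at least 2-fold, edgeR's quasi-likelihood test). The counts at an unadjusted p under 0.05 were 7046 and 6864. With upper-quartile scaling 3869 genes were higher and 2233 lower in parental cells, and 3638 and 2316 in KD cells. The balance of directions thus depended on the scaling. Mitotic genes fell with medians of -1.23 in parental and -1.36 in KD cells, 32 of 32 in each when adjusted over the list alone (camera, adjusted p = 1.74e-17 and 1.02e-17, and adjusted p = 0.0528 and 0.0515 with an estimated correlation). The kinase genes Aurkb and Plk1 fell by -1.57 ± 0.08 and -1.46 ± 0.09 in parental cells. S phase genes fell in 30 of 33 cases in parental and 32 of 33 in KD cells, 31 and 32 lower when adjusted over the list alone (adjusted p = 0.0901 and 0.0596 with an estimated correlation). E2f2 rose in both, a call lost in parental cells without parental DMSO replicate 1 (adjusted p = 0.05003) and in KD cells without KD DMSO replicate 1, KD DMSO replicate 2 or KD largazole replicate 2 (adjusted p = 0.0889, 0.0582 and 0.0751). The other parental exceptions were Ccne1 (0.12, adjusted p = 0.508) and Ccne2 (-0.31, adjusted p = 0.0592). The helicase subunit Mcm5 fell by -1.63 ± 0.08 in parental and -2.12 ± 0.08 in KD cells and the ribonucleotide reductase subunit Rrm2 by -1.47 ± 0.09 and -2.11 ± 0.09. Homologous recombination and Fanconi genes had medians of -0.996 and -1.57, 18 of 18 in each when adjusted over the list alone (adjusted p = 0.129 and 0.0673 with an estimated correlation). Cholesterol synthesis genes fell in 19 and 21 of 24 cases, with Tm7sf2 higher, 19 and 21 adjusted over the list alone (camera, adjusted p = 9.47e-08 and 4.47e-09, and adjusted p = 0.0901 and 0.0596 with an estimated correlation). They included Acat2 (-1.69 ± 0.08 and -1.75 ± 0.08) and Idi1 (-1.43 ± 0.08 and -1.54 ± 0.08). Integrated stress response genes fell in 18 and 19 of 24 cases, 18 and 20 adjusted over the list alone (adjusted p = 0.198 and 0.0967 with an estimated correlation). Ddit4 and Cebpb, a transcription factor gene, rose in both genotypes. The count of 2 that rose was 1 in parental cells without any 1 parental or KD DMSO library, and 1 in KD cells without KD DMSO replicate 2 or KD largazole replicate 1. The mitochondrial folate enzyme Shmt2 stood at -1.26 ± 0.08 and -1.54 ± 0.08 and Slc7a11 at -0.998 ± 0.132 and -2.25 ± 0.14.

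Neuronal genes rose in 13 of 19 cases in each genotype, 15 and 14 adjusted over the list alone (camera, adjusted p = 8.41e-05 and 5.36e-05, and adjusted p = 0.0901 and 0.0596 with an estimated correlation). The neurofilament genes Nefl and Nefm fell in both genotypes and Gap43, a gene of axon growth, in KD cells. In KD cells the call of Nefl was lost without KD DMSO replicate 2 (adjusted p = 0.0707) and that of Gap43 without KD DMSO replicate 1 (adjusted p = 0.0691). These 3 genes were named after their values were seen. Uchl1, a neuronal ubiquitin hydrolase, went from 1.69 ± 1.14 to 134 ± 30.3 CPM in KD cells. Vgf, a neuropeptide precursor, had 468 counts under largazole and 3 in DMSO in parental cells, a ratio of 148 (95% interval 50.4 to 721). The synaptic vesicle gene Syp had 403 counts under largazole and 1 in DMSO in parental cells, a ratio of 383 (95% interval 68.3 to 15149). Asic1, an acid-sensing ion channel with 0 counts in parental DMSO, was at least 52.2-fold higher under largazole, against a floor of 3 counts per library. Epithelial junction genes rose in 10 of 12 cases in each genotype, 10 adjusted over the list alone (camera, adjusted p = 0.000224 and 2.41e-05, and adjusted p = 0.0985 and 0.0596 with an estimated correlation). Jup, the junction protein plakoglobin, went from 28.8 ± 2.33 to 94.2 ± 0.0520 CPM in parental and from 28.2 ± 1.80 to 110 ± 5.77 in KD cells. Keratinocyte differentiation genes rose in 7 and 6 of 10 cases, 8 and 7 adjusted over the list alone (adjusted p = 0.171 and 0.144 with an estimated correlation). Among them were the corneodesmosome gene Cdsn (3.62 ± 0.20 and 4.75 ± 0.33) and the cornified envelope gene Sprr1a (2.59 ± 0.30 and 2.29 ± 0.30). Glutathione genes rose in 17 and 16 of 28 cases and fell in 4 and 5. The numbers risen were the same when adjusted over the list alone (adjusted p = 0.65 and 0.582 with an estimated correlation). The number fallen in KD cells was 2 without either KD DMSO library and 3 without KD largazole replicate 2. The transferase Gsta4 went from 0.747 ± 0.198 to 29.3 ± 0.632 CPM in parental cells. In a list of genes often raised by HDAC inhibitors, 9 of 14 rose in parental cells and 3 fell, the latter a count that was 1 without parental DMSO replicate 2 or parental largazole replicate 2. The number risen was 9 when adjusted over the list alone (camera, adjusted p = 0.00607, and adjusted p = 0.594 with an estimated correlation). Txnip, an inhibitor of thioredoxin, rose by 3.14 ± 0.10, the chaperone Clu by 2.47 ± 0.10 and the metallothionein Mt2 by 2.41 ± 0.19, while Cdkn1a, Glrx and H1f0 fell. In KD cells that list was not called (adjusted p = 0.069).

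Of the ER chaperone genes 17 of 20 fell under largazole in KD cells, 18 adjusted over the list alone (camera, adjusted p = 8.34e-07, and adjusted p = 0.0601 with an estimated correlation), while in parental cells 5 rose, 4 fell and 11 did not pass (camera, adjusted p = 0.922). The parental counts depended on single libraries. Without parental DMSO replicate 1 and replicate 2 and parental largazole replicate 1 and replicate 2, in that order, 3, 0, 0 and 3 rose and 1, 2, 1 and 2 fell, and 3 rose without KD DMSO replicate 2. Interferon-stimulated genes rose in 11 of 32 cases in parental cells, 10 adjusted over the list alone (camera, adjusted p = 0.0135, and adjusted p = 0.826 with an estimated correlation), a count that was 5 without parental DMSO replicate 1. In KD cells this list was not called, with a median of -0.05 (camera, adjusted p = 0.723), but it was called lower without KD DMSO replicate 2 (median -0.44, adjusted p = 0.00367), and its median was 0.37 without KD DMSO replicate 1 (adjusted p = 0.176). Ribosome biogenesis genes fell in 13 of 27 cases in parental and 22 of 27 in KD cells, with the same numbers adjusted over the list alone (adjusted p = 0.184 and 0.0596 with an estimated correlation). In parental cells Bop1 and Myc rose, a count of 2 that was 1 without either KD DMSO library, and both calls were lost without any 1 parental library. The parental count of fallen genes was 8 without parental DMSO replicate 1, parental DMSO replicate 2 or parental largazole replicate 2, and 7 without parental largazole replicate 1. The epithelial junction count in KD cells was 6 without KD DMSO replicate 2. Hdac1 rose by 0.46 ± 0.08 in parental cells (adjusted p = 0.000723). Its change of 0.22 in KD cells (adjusted p = 0.0374) missed the threshold without any 1 library other than KD largazole replicate 2 (adjusted p = 0.0515 to 0.258). Hdac2 fell by -0.40 ± 0.08 in parental cells (adjusted p = 0.00302) and had -0.18 in KD cells (adjusted p = 0.0915), which passed without KD largazole replicate 1 (adjusted p = 0.00947). Hdac3 had -0.05 in parental (adjusted p = 0.644) and -0.28 in KD cells (adjusted p = 0.0219, but 0.0862 without KD DMSO replicate 1 and 0.0863 without replicate 2). Gpx4 rose by 0.65 ± 0.14 in KD cells (adjusted p = 0.00364) and by 0.50 in parental cells (adjusted p = 0.0131), the latter lost without parental DMSO replicate 1 or 2 or parental largazole replicate 1 (adjusted p = 0.0662, 0.079 and 0.0955). Cdkn1a fell by -0.48 ± 0.09 in KD cells (adjusted p = 0.00153), and its parental change of -0.25 (adjusted p = 0.0405) was lost without any 1 parental library or KD DMSO replicate 1 (adjusted p = 0.0573 to 0.142). Other genes that fell included Adcy8, an adenylyl cyclase (-3.73 ± 0.33 in parental cells), Neil3, a DNA glycosylase (-3.02 ± 0.21), Nptx1 (-2.69 ± 0.14), Plxna4 (-2.49 ± 0.18) and Mmp3 (-2.74 ± 0.12 in KD cells).

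The responses of the genotypes to largazole were then compared with each other, which asks whether lowering PRDX6 alters the effect of the drug. Hspa5 (chromosome 2, 34771970 to 34777547, plus strand, GRCm38) fell in KD cells from 1260 ± 52.1 to 451 ± 0.453 CPM and stood at 2334 ± 24.4 and 2637 ± 27.9 CPM in parental cells (SD, n = 2), a difference in response of -1.66 ± 0.10 on the log2 scale. Other ER chaperone genes went the same way, with Herpud1 at -1.21 ± 0.13, Creld2 at -1.13 ± 0.15 and Pdia4 at -0.99 ± 0.10. Slc7a11 (-1.26 ± 0.20), Trib3 (-1.14 ± 0.16) and the S phase endonuclease gene Fen1 (-0.85 ± 0.12) fell more in KD than in parental cells. Il33 fell less in KD cells (1.11 ± 0.11), and Bnip3 rose in KD and fell in parental cells (0.97 ± 0.14).

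The difference passed for 26 genes (4 positive and 22 negative, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 1087 had an unadjusted p under 0.05. Of the ER chaperone genes 7 of 20 passed, 16 adjusted over the list alone, with a median of -0.64 (camera, adjusted p = 1.21e-17, and adjusted p = 0.0598 with an estimated correlation). Camera called 11 lists for this difference, and none with an estimated correlation. Besides the ER chaperones they were S phase (median -0.43, adjusted p = 1.75e-15, and 0.0925 with an estimated correlation), homologous recombination (-0.53, 1.57e-08 and 0.197), interferon-stimulated genes (-0.88, 5.44e-08 and 0.552), the integrated stress response (-0.28, 6.67e-07 and 0.213), ribosome biogenesis (-0.27, 3.27e-06 and 0.111) and glycolysis and hypoxia (0.11, 5.69e-06 and 0.344). The others were genes often raised by HDAC inhibitors, p53 targets, cholesterol synthesis and mitosis, all with negative medians (adjusted p = 0.000804 to 0.0362, and 0.262 to 0.552 with an estimated correlation). The call of the first was lost without parental largazole replicate 1 or KD largazole replicate 2. The calls of p53 targets, cholesterol synthesis and mitosis were each lost without either parental DMSO library, parental largazole replicate 1 or KD DMSO replicate 2. Those of cholesterol synthesis and mitosis were also lost without parental largazole replicate 2, that of cholesterol synthesis without KD largazole replicate 1 and that of mitosis without KD largazole replicate 2. Few members of these other lists passed singly. They were 2 in S phase, 3 in the integrated stress response, 1 in glycolysis and hypoxia and 1 among genes often raised by HDAC inhibitors. In the homologous recombination, interferon, ribosome biogenesis, p53, cholesterol synthesis and mitosis lists 0 members passed. The interferon median was -0.47 without KD DMSO replicate 1, and that of glycolysis and hypoxia 0.22 without KD largazole replicate 2. Hspa5 passed (adjusted p = 0.000144) in each of the 20 other settings in which the difference could be tested. The number of genes was 2 or 3 without any 1 parental library or KD DMSO replicate 1, 11 without KD DMSO replicate 2, and 428 and 457 without KD largazole replicate 1 and replicate 2. The ER chaperone count was 1 without any 1 parental library or KD DMSO replicate 1, 2 without KD DMSO replicate 2 and 14 without either KD largazole library. The calls of Slc7a11, Trib3, Fen1, Bnip3, Creld2 and Pdia4 were lost without any 1 parental or KD DMSO library, and those of Herpud1 and Il33 in the same fits other than that without KD DMSO replicate 2. Without these libraries the adjusted p was 0.13 to 0.37 for Slc7a11, 0.0531 to 0.307 for Trib3, 0.144 to 0.331 for Fen1, 0.106 to 0.216 for Bnip3, 0.0531 to 0.123 for Herpud1 and 0.0531 to 0.08 for Il33. DESeq2 called 83 genes, and a fit with the replicate number as a block called 104. With the length trend removed 43 passed, and with length and GC trends removed 54. The Hdac1, Hdac2, Hdac3, Cdkn1a and Gpx4 differences were -0.25, 0.21, -0.23, -0.23 and 0.15 (adjusted p = 0.555, 0.695, 0.669, 0.681 and 0.932), and that of Gpx4 passed without KD largazole replicate 2 (adjusted p = 0.0319).

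Most of the largazole response was common to both genotypes. Of 4917 genes changed in both, 4903 changed in the same direction, and 2649 were higher in both and 2254 lower in both, where independent lists would share 840 and 659. Across the 12517 genes, which are not independent replicates, the log2 fold changes had r = 0.885 and rho = 0.885, and these comparisons share no library. Of 2249 genes with at least a 2-fold mean response, 44.7% had the larger fitted response in KD cells, 37.6% of the 1715 raised and 67.6% of the 534 lowered genes. The share was 50.2% without KD DMSO replicate 1, so the side of the even split that it fell on depended on that library.

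**Figure D4:**
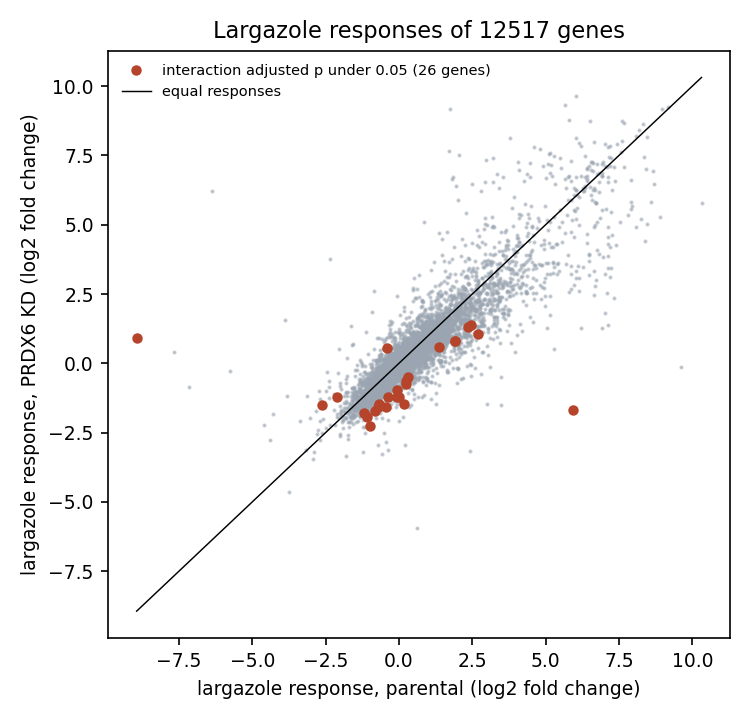
Log2 fold change under largazole in parental cells (horizontal axis) and in KD cells (vertical axis) for 12517 genes (grey), with the 26 genes whose responses differed in red and a line of equal responses. The red points far to the left and right are Gm5424 and Ass1, whose fitted values at low counts depend on the prior count.

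**Figure D5:**
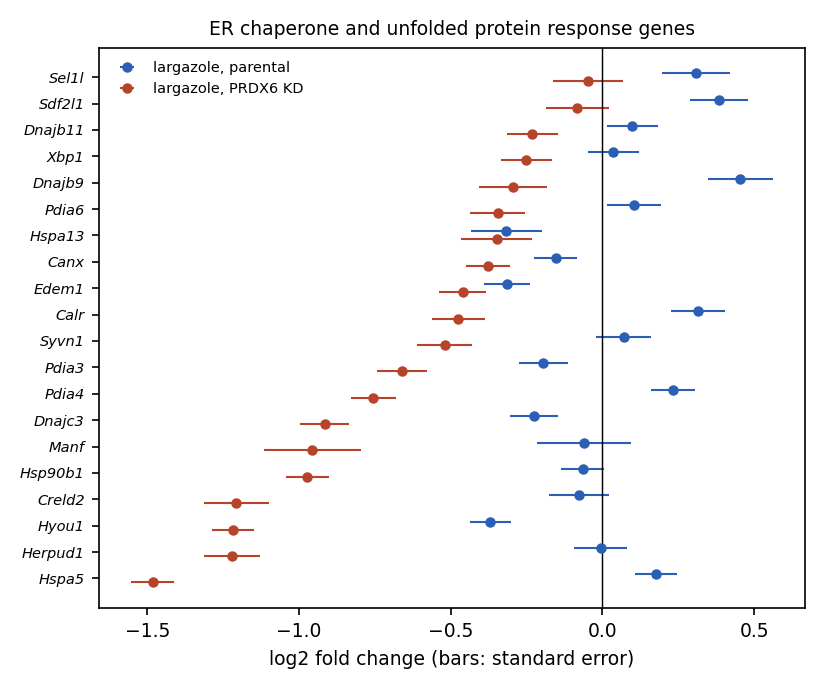
Log2 fold change under largazole (horizontal axis) for the 20 tested ER chaperone and unfolded protein response genes (vertical axis), in parental (blue) and KD cells (red), with bars of 1 SE. In KD cells 17 of the 20 genes fell.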

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

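The tests of the summed Ass1 and Gm5424 counts, of immune cell markers and of the knockdown construct were chosen after the results were seen. The removal of length and GC trends was also added after seeing the data. All 26 genes below were picked out because the response to largazole differed between genotypes in the interaction test of edgeR, with an adjusted p under 0.05. Values are log2 differences, KD response minus parental response. Genes outside the rule for named genes, such as Gm5424 and Odc1, are named because they passed, after their values were seen.

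Ass1, argininosuccinate synthase, had -7.61 (parental response 5.93, KD response -1.67) and Gm5424, a processed pseudogene, 9.86 (-8.94 and 0.92). Gm5424 had 0 counts in parental largazole, so its fitted values depend on the prior count and give no bound. Ass1 lies on chromosome 2 (31470207 to 31520672) and Gm5424 on chromosome 10 (62071123 to 62072362). Of the 30-base windows of the Ass1 transcript, 61.8% occur exactly in Gm5424. A candidate explanation for the opposite directions is that reads of a single transcript were divided differently between these genes. In DMSO Gm5424 stood at 4.27 ± 0.0730 CPM in parental and 14.3 ± 0.297 in KD cells. Under largazole it stood at 0 ± 0 and 27.1 ± 0.756 CPM (SD, n = 2). Such a division would have to repeat in both replicates of a group, which was not tested. The summed counts stood at 4.64 ± 0.450, 21.9 ± 0.720, 22.1 ± 0.276 and 29.4 ± 3.02 CPM in parental DMSO, KD DMSO, parental largazole and KD largazole (SD, n = 2). The sum had an interaction of -1.83 ± 0.20 (adjusted p = 0.00662), so a smaller genotype difference in the response of the pair stays open.

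The ER chaperone genes Hspa5 (-1.66), Herpud1 (-1.21), Creld2 (-1.13), Pdia4 (-0.99), Hsp90b1 (-0.91), Hyou1 (-0.85) and Calr (-0.79) were all more negative in KD cells. Trends with length and GC content are argued against as the cause, since the median over the 20 list members was -0.637 after their removal and -0.640 before. A single library also fails to account for it, as the highest median over the 8 fits without 1 library was -0.615, and so does library scaling, with a highest median of -0.628 over 3 other scalings. A difference between these lines in the ER response to largazole, or to the 18 h that came with it, may underlie the pattern. This is a hypothesis found and tested on the same data. Clonal differences between the lines and a response to the knockdown construct itself were not tested and stay open.

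Interferon-stimulated genes were higher in KD than in parental cells in DMSO, a knockdown effect that was weighed for its size. Immune cells in the cultures are argued against by 18 immune markers, of which 0 were both above 5 CPM in a KD group and raised by the knockdown. Cd68 was the highest of them, at 4.28 CPM of library totals in KD DMSO and 4.08 in parental DMSO. A single library does not account for the pattern, since at least 26 of 32 genes rose in DMSO in each of the 8 fits without 1 library. That test covered DMSO only. Under largazole fewer of these genes passed without parental largazole replicate 1 or replicate 2. The list's median log2 fold change under largazole was 2.13, and at least 1.999 without any 1 library. A response to the knockdown construct itself and an effect of lower PRDX6 cannot be told apart, because 0 libraries carry a construct with no target, and either may be the cause.

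In the other genes the values were as follows. The stress response genes had -1.26 (Slc7a11), -1.14 (Trib3) and -0.89 (Chac1). The matrix and surface genes Loxl2 and Thy1 had -1.09 and -1.08, Clu -1.08, the ribonuclease gene Rnase4 -1.04 and the protease gene Mcpt8 -1.66, all raised less in KD cells. Mcpt8 went from 9.45 ± 0.187 to 61.6 ± 1.52 CPM in parental and from 96.3 ± 1.43 to 199 ± 35.0 in KD cells (SD, n = 2). Cited2 had -0.80, Cyr61 -0.79 and Odc1, the first enzyme of polyamine synthesis, -0.89. The replication and repair genes had -0.85 (Fen1), -0.84 (Fignl1) and -0.61 (Mcm6). Positive differences were 0.89 for Itgbl1, 0.97 for Bnip3 and 1.11 for Il33. With the exception of Hspa5 and Gm5424, most of these calls were lost without 1 parental or KD DMSO library, as only 2 or 3 genes passed without any 1 parental library or KD DMSO replicate 1, and 11 without KD DMSO replicate 2.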

How the results depend on the processing

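Removal of Rn45s and of length and GC trends was added after seeing the data, and the other alternatives were chosen before. Over the 10 main results, 168 alternative values lay within their limits, 15 moved beyond them, 10 counts were over 1.5 times higher and 13 lower. For named genes 6920 calls were the same, 367 were lost and 19 gained, and for gene lists 2237 were the same, 116 lost and 47 gained. None reversed among these. Of the list calls 60 were lost with an estimated correlation in camera, which left 4 of 15 for the knockdown in DMSO, 6 of 15 under largazole and none for the largazole responses or their difference. Fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, gave 30 of the gains and 11 of the losses.

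With 1 library left out in turn, the number of genes changed by largazole ranged from 4234 to 7834 in parental and 4352 to 7065 in KD cells, that changed by the knockdown from 398 to 2969 in DMSO and 837 to 4175 under largazole, and the number with differing responses from 2 to 457. The share of responding genes with the larger response in KD cells ranged from 42.4% to 50.2%, against 44.7%, and the correlation of the responses from 0.835 to 0.850, against 0.885. The highest counts came without a KD largazole library, where the common coefficient of variation was 0.0602 against 0.0946, so the spread between those 2 libraries sets part of the counts. Without 1 of the others fewer libraries and a larger spread remained.

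With only the libraries compared, 3266 genes changed with the knockdown in DMSO and 965 under largazole. The spread, the filter and the scaling then came from those 4 libraries alone. Over all 8 libraries, other scalings gave 1261 to 1374 genes in DMSO and 2205 to 2297 under largazole, against 1380 and 2293. No filter and a stricter filter gave 1149 and 1367 in DMSO and 1973 and 2266 under largazole. Scaling or filter alone thus moved the counts less, and the spread was not varied on its own. The number of genes with differing responses was 83 with DESeq2, 43 with the length trend removed and 54 with length and GC trends removed, against 26, and the cause was not tested. The correlation of the responses was 0.621 with no filter, 0.912 with the stricter filter and 0.896 with limma-voom. The filter acts through the number of low-count genes included, and for limma-voom the cause was not tested.

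The replicate numbers were fitted as a replicate block, which gave 6971 and 6757 genes changed by largazole, 2033 and 3103 by the knockdown and 104 with differing responses. The correlations of same-numbered deviations between groups were 0.146, 0.00167, -0.00767, 0.273, 0.364 and 0.343, of which 4 of 6 were over 0.1. As not all were, and the labels name no shared batch or day, the main fit did not pair the samples. The values 0.00167 and -0.00767 both involved parental DMSO, whose replicates differed least. The SD of their log2 difference was 0.194, against 0.218 in parental largazole, 0.207 in KD DMSO and 0.359 in KD largazole. How far these 2 values speak against pairing stays open, and the values among the other groups were 0.273, 0.364 and 0.343. Rn45s was higher in replicate 1 than in replicate 2 of all 4 groups, and the block lowered the common coefficient of variation to 0.0748, so a difference shared by libraries of the same number stays open. Depth limits genes near 0 counts, where folds are bounds or ratios, and 2 replicates per group limit all of these tests, most of all that of the difference between responses.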

Other observations

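The 35 ways to split the 8 libraries into 4 and 4 were planned as a test, and nothing else in this part was tested beyond the comparisons already made. All members named here were chosen after their values were seen.

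Largazole raised the 3 tested MHC class II genes in both genotypes, and the list's other members were not tested. Cd74 and H2-DMb1 held 2 and 7 counts in parental DMSO and 1 and 4 in KD DMSO, under the filter's minimum. They were tested only through the largazole libraries, so the filter favoured a rise. The count of 3 is therefore no evidence for the list as a whole. H2-DMa rose by log2 fold changes of 3.84 ± 0.37 in parental and 3.28 ± 0.42 in KD cells (SE, edgeR). H2-DMb1 rose by 2.13 ± 0.64 and 3.86 ± 0.63, the first a call lost without parental DMSO replicate 1 (adjusted p = 0.135) or parental largazole replicate 1 (adjusted p = 0.139). Cd74, the invariant chain, had 76 counts under largazole and 2 in DMSO in parental cells, a ratio of 36.1 (95% interval 9.65 to 303), and 122 and 1 in KD cells, a ratio of 127 (22.3 to 5051). The list had too few tested members for a set test. Cd68, a lysosomal glycoprotein best known from macrophages, rose by 3.89 ± 0.14 and 3.33 ± 0.14, to 63.6 CPM of library totals in parental and 44.7 in KD cells.

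Lysosome and autophagy genes rose under largazole in 18 of 30 cases in parental and 19 of 30 in KD cells, 19 in each when adjusted over the list alone, while 3 and 1 fell (camera, adjusted p = 0.00382 and 0.0006, and adjusted p = 0.616 and 0.506 with an estimated correlation). The 3 that fell in parental cells were 1 without any 1 parental library, and the 1 that fell in KD cells was 2 without either KD largazole library. Atp6v0d1, a subunit of the proton pump, rose by 1.60 in parental and 1.29 in KD cells, and Map1lc3b, an autophagosome protein, by 1.49 and 1.22.

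Of the 35 splits of the 8 libraries into 4 and 4, the real one, largazole against DMSO, gave 6126 changed genes in a test of these 2 groups. The highest of the others gave 254. That highest split was the one between genotypes. A share of 1 in 35 is the lowest that this design can give. Splits that mix drug and DMSO libraries hold the drug effect as spread within groups, which lowers their counts. The labels also do not say that the 8 libraries are independent. The test therefore cannot exclude chance as the source of the largazole effect.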
